A study of Glycine max with 3 samples.

How the data were processed

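Small RNA was sequenced from 2 libraries, 1 of control and 1 of chilled leaves, and a degradome from 1 library of both kinds of leaves mixed. Per the labels' protocols, the plants grew at a photon flux density of 600 μmol per square metre per second with 12 h of light and a humidity of 50% to 85%, 10 pots were prepared for each condition, leaves of 3 replicates were pooled in each condition, about 1 μg of total RNA entered an Illumina TruSeq small RNA library, and reads were single-end from an Illumina sequencer. The degradome library's label gives a stage of 10 days after pollination, which differs from the stage of the other libraries and could not be settled; its tissue is given as leaf. The read trimming, aligner, miRNA caller, target caller, miRBase release and genome build are not given in the sources used here.

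The profile tables hold reads per miRNA for each library, called raw reads per the file headers. Of the 587 entries, 339 hold fractions in at least one library, so the deposited values may be expected counts (estimated counts of reads shared out over loci). They are not scaled to depth. Whether each entry of a sequence holds all of its reads or a share is not given. The plan had assumed normalised reads; the raw reads were scaled here instead. The same deposited tables give the GC percent of each hairpin, its folding energy and its coordinates, which count from 1; these hairpin properties were not tested. The degradome table holds, per the file headers, an abundance of reads at the cut site named TPB (a normalised signal that the authors did not spell out), an alignment score, a category from 0 to 4 and a p-value for each pair, all as the authors deposited them. Coordinates are printed as deposited, and no genome was used. In 6 lines of the known miRNA table the content was empty in the copy used here; these lines are not analysed here. In 497 of the 587 entries the mature sequence occurs exactly in the hairpin sequence given, and in 90 it does not; 7 distinct sequences contain an undetermined base. Names are the authors', with the soybean prefix gma left out, and 9 sequences carry names of other species.

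One entry was kept per distinct mature sequence, the one with the most reads, so 381 sequences remained, 106 of them listed at more than 1 locus. For 12 sequences the entries differed in reads. Over all entries the reads summed to 4168480 in the control and 5655446 in the chilled library. If entries hold shares of a sequence's reads, keeping 1 entry leaves reads out of the sums, family values and shares given here. Reads of isoforms and paralogs can be shared between entries, so family sums and sequence values of near-identical members are uncertain. Counts were rounded to whole numbers for scaling and intervals. Both libraries were scaled with edgeR 4.0.16 (TMM, in R 4.3.3), which set the chilled library 0.25 above the control on the log2 scale; DESeq2 1.42.0 size factors set it 0.30 above. Against TMM, the same table total moved the scale of the chilled library by 0.23, which lowers every log2 ratio by that much, a total without miR3522 moved it by -0.21 and unscaled reads by -0.25, which raises every log2 ratio. Under TMM the median log2 ratio of the tested sequences was 0.06, and directions are given relative to that scaling.

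The log2 ratio is that of chilled to control normalised reads, each with a pseudocount of 1. A sequence was called higher or lower where this ratio was at least 1 either way and at least one library had 10 normalised reads. Intervals of ratios are exact conditional binomial intervals at 95%, and intervals of shares are Wilson intervals; for ratios and shares of reads they cover counting error only, and a count of 0 allows up to 3 reads. The number of calls that counting error alone gives was found from 1000 simulations of Poisson reads at the mean of both libraries. No test between conditions was made, since each had 1 library, and the Fisher test planned for miRNAs with a degradome target is given as an odds ratio without its p-value for the same reason. Lists of families were fixed before the data were examined, and each list's median was placed among 10000 random lists of the same size drawn from families in the same of 5 bins of mean abundance.

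Target classes per family were written before the data were examined, as patterns searched for in the target annotation. The test shuffled classes over families 100000 times, keeping all targets of a family together. The sequences named were those with the 10 highest and the 10 lowest log2 ratios among sequences above the minimum and the 10 with the highest mean, each family of the fixed lists by its sum, and, in the degradome, the target with the lowest category, then the lowest p-value, then the first identifier, for each such family and each sequence named by ratio. Other sequences and targets named in the text were chosen after their values were seen. One first target, of miR172, is not reported here. The scripts were tested on simulated data: with 60 of the 381 sequences set to known folds in 50 simulations, 46.8% of sequences at 2-fold, 99.6% at 4-fold and 100% at 8-fold were called in the right direction, 3.83% of unchanged sequences were called, and a set depth difference of 0.25 was recovered as 0.249. These simulations held counting error only, with as many sequences set higher as lower. They cannot show which scaling is right for the real libraries.

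Alternatives comprised other scalings, pseudocounts and minimums, every entry of the tables, known miRNAs alone, stricter degradome categories and p-values, 1 entry per gene locus and shuffling of single pairs. The authors' own list of chilling-responsive miRNAs is not analysed here. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.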

Results

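Small RNAs were sequenced from leaves of the vegetable soybean (Glycine max) cultivar Taiwan 75, a soybean eaten as immature seed, at the stage of 1 true leaf. One library came from control plants kept at 25 °C by day and 17 °C by night, and one from plants held at 4 °C for 24 h; in each condition 3 replicates were pooled before sequencing. A further library, of mixed chilled and control leaves, was a degradome library. It sequences the 5′ ends of cut messenger RNAs, among which sites that a miRNA may have cut can be sought. With 1 library per condition the difference between conditions has no replicate check, and the ratios below compare those 2 libraries. The profile tables held 381 distinct mature sequences of 136 families, 378 matched by the authors to known miRNAs and 3 listed by them as new. Over these sequences the control library summed to 3856902 reads and the chilled library to 5347700 reads. These sums take 1 entry per sequence, against 4168480 and 5655446 reads over all entries. The depth of the whole libraries is not given in the sources used here. Reads were not counted by molecular identifiers, so the intervals of ratios and of shares of reads cover counting error only.

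The leaf profile was dominated by miR3522. Its shares below are of the sums with 1 entry per sequence, and would be smaller over all entries. Its 21-nt sequence TGAGACCAAATGAGCAGCTGA, from a hairpin at 4337686 to 4337777 on the plus strand of chromosome 15, took 87.9% of the control table's reads (95% Wilson interval 87.9 to 88.0) and 91.0% of the chilled table's (91.0 to 91.0). After scaling, its log2 ratio of chilled to control was 0.27 (95% interval 0.27 to 0.28). Next in mean abundance were miR1510b-5p, of a family that targets disease resistance genes, with a log2 ratio of -0.86 (-0.87 to -0.84), and the 5′ arm of the miR408a hairpin, of a family tied to copper supply. The degradome loci of the miR1510 family were listed first for another member, miR1510a-3p, at -0.48. The 5′ arm of miR408a had a log2 ratio of 0.18 (0.17 to 0.20) and its 3′ arm -0.75 (-0.77 to -0.72); the 5′ arm's ratio turned to the other side of 0 when the libraries were set to the same table total. Among the other abundant sequences, miR167c stood at -0.31, miR1509a at 0.48, miR1508a at 0.66 and miR167e at 0.06, the last of a sign that changed between scalings. miR4996 fell just short of the rule of size given below, at -0.999 (-1.03 to -0.97), and met it under the DESeq2, median and table-total scalings. miR1507a, a 22-nt miRNA whose family targets disease resistance genes, was the sequence among the 10 most abundant that met the rule of size, at 28363 chilled and 11161 control reads and a log2 ratio of 1.10 (1.07 to 1.13); it no longer met it under the same table total.

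The main question of the study was which miRNAs differ after chilling. Chilled leaves had more of miR164a, which targets NAC transcription factors, and of 5 low-abundance sequences among 14 tested of the miR169 family, which targets subunit A of nuclear factor Y. Of these, miR169l-3p and MIR169a-p3 come from the 3′ arm. The others, miR169c and the sequences listed as miR169e, overlap almost fully and can share reads. miR169b (0.10) and miR169u (-0.77) were not higher. Chilled leaves had less of miR156a and miR156r, which target SPL transcription factors of the juvenile-to-adult transition, and of miR4413 and miR172b-5p. Of 213 sequences with at least 10 normalised reads in one library, 30 were at least 2-fold higher and 35 at least 2-fold lower in the chilled library, and 148 were neither. The counting interval excluded a ratio of 1 for 26 of the higher and 33 of the lower sequences, and lay wholly beyond 2-fold for 10 and 17 of them. Counting error alone gave a mean of 3.36 higher and 2.67 lower sequences in 1000 simulations. The split moved with scaling: 19 higher and 52 lower with the same table total, 47 higher and 25 lower with unscaled reads, 40 higher and 26 lower with a table total that left out miR3522, and 7 higher and 14 lower at a minimum of 100 normalised reads. Under each of the 6 scalings run, 19 of the 30 higher and 25 of the 35 lower sequences met the rule.

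**Figure D1:**
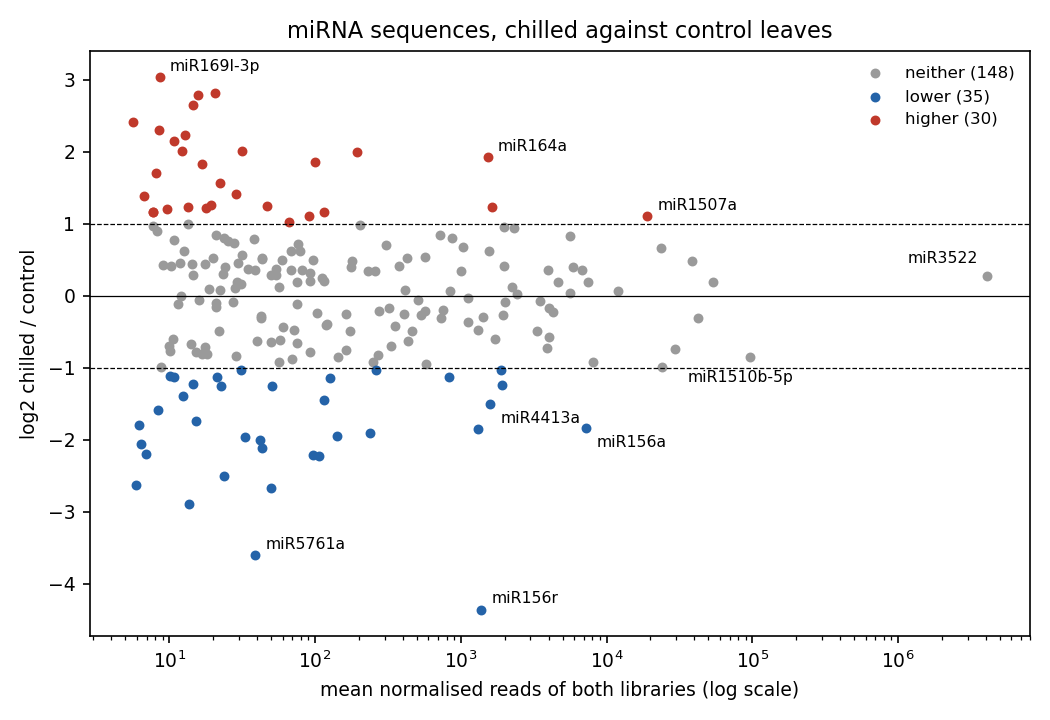
Log2 ratio of chilled to control (vertical axis) against the mean normalised reads of both libraries (horizontal axis, log scale) for the 213 sequences above the minimum, 1 point per sequence, with no error bars. The 30 higher sequences are red and the 35 lower ones blue; most of the higher ones lie at low abundance, while miR156r, at -4.36, is both abundant and the lowest.

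The 10 highest ratios belonged to low-abundance sequences. miR169l-3p had 1 control and 17.5 chilled reads, a log2 ratio of 3.03 (1.26 to 9.30). MIR156l-p3, with 4 and 40 reads, had a ratio of 2.82 (1.61 to 5.02), MIR156m-p3, with 3 and 31 reads, 2.79 (1.44 to 5.48), and MIR171b-p5, with 3 and 28 reads, 2.65 (1.28 to 5.34); names ending in p3 or p5 are the authors' names for the opposite arm of a known hairpin. MIR4383-p3 followed at 2.41, MIR169a-p3 at 2.30, miR169c at 2.24, the 2 sequences listed as miR169e at 2.15 and 2.01, and miR5559 at 2.01. More abundant was miR164a, chosen after its values were seen, with 584 control and 2634 chilled reads and a log2 ratio of 1.93 (1.80 to 2.06); its sequence is listed at 10 loci.

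The lowest ratio was that of miR156r, whose single hairpin lies at 6633951 to 6634116 on the plus strand of chromosome 16. It had 2402 control and 137 chilled reads, 20.6-fold lower after chilling, with a log2 ratio of -4.36 (-4.64 to -4.13). miR5761a followed at -3.60 (-5.20 to -2.51), then miR159d at -2.90 (-5.56 to -1.46) and miR172b-5p at -2.68 (-3.70 to -1.93). MIR5032-p3 stood at -2.63, MIR4413a-p3 at -2.51, MIR5372-p3 at -2.23, MIR159d-p3 at -2.22, MIR171e-p5 at -2.19 and miR4413b at -2.12. Both arms of the miR159d hairpin and both miR4413a arms thus lay below 0, with miR4413a itself at -1.51 (-1.63 to -1.40); that last sequence was chosen after its values were seen. Of the 3 sequences listed as new, miRN3 was higher, with 25 control and 72 chilled reads and a log2 ratio of 1.25 (lower bound 0.61), and miRN1 (0.84, -0.11 to 1.88) and miRN2 (-0.62, -1.17 to -0.05) did not meet the rule.

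Families were then compared in lists fixed before the data were examined. Among 9 detected families that target growth and phase-change transcription factors, miR164 was 3.76-fold higher in sum (log2 1.91, 1.78 to 2.04), and no other family sum differed 2-fold. These sums add all sequences of a family, opposite arms included. miR156 (-0.57, -0.60 to -0.54), miR159 (-0.51), miR172 (-0.56, -0.63 to -0.49) and miR319 (-0.54, -1.61 to 0.45, from 20 and 16 reads) lay below 0 under each scaling, and miR169 (0.46, 0.33 to 0.59) and miR396 (0.28) above 0. The miR396 sum pooled sequences on both sides of 0, named after their values were seen. miR396b-3p stood at 0.95, while miR396a-3p (-0.09), miR396b-5p (-0.50), miR396j (-0.86), miR396a-5p (-1.03) and MIR396j-p5 (-1.80) lay below 0. The growth-regulating factor loci of the degradome were listed first for miR396a-5p. miR166 (-0.05) and miR171 (0.12) changed sign between scalings. Of the list's 64 sequences above the minimum, 14 were higher, 12 lower and 38 neither; the list's median of -0.05 over families stood at percentile 60.7 of 10000 random lists of the same size matched on abundance, and turned to 0.21 over sequences. miR156 held members on both sides, with miR156a (20 nt, 10368 control and 3431 chilled reads) at -1.84 (-1.90 to -1.79) and miR156c (21 nt) at 0.42 (0.33 to 0.51). The 5 members that share a core sequence, with most of their reads from miR156a, pooled to -1.37 (-1.42 to -1.33). Their upper bound was -1.09 over the scalings run, so this pool was more than 2-fold lower. The 13 opposite arms pooled to 0.82 (0.77 to 0.88). Both pools were formed after the values were seen.

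**Figure D2:**
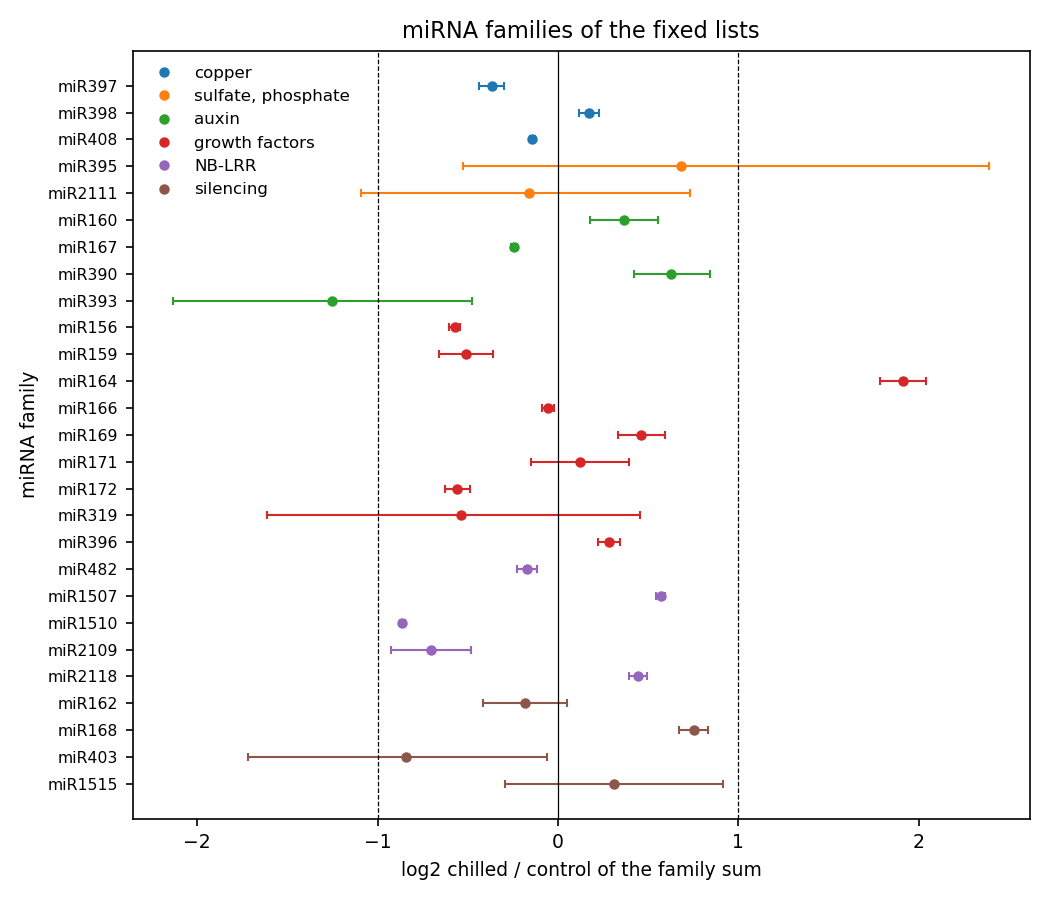
Log2 ratio of chilled to control of the family sum (horizontal axis) for each miRNA family of the fixed lists with at least 20 normalised reads over both libraries (vertical axis), coloured by list. Bars are exact 95% intervals for counting error; miR164, at 1.91, and miR393, at -1.26, lie beyond the dashed 2-fold lines, and values near 0 such as those of miR166, miR171, miR162, miR482, miR408, miR398, miR167 and miR2111 changed sign between scalings.

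Of the auxin-related families 1 met the 2-fold rule. miR393, which targets the auxin receptors, was 2.39-fold lower in sum (log2 -1.26, -2.13 to -0.48), on 41.2 control and 19.8 chilled reads. miR390 (0.63, 0.42 to 0.84) and miR160 (0.37, 0.17 to 0.56), which act on auxin response factors, lay above 0 under each scaling, and miR167 (-0.24) turned above 0 with unscaled reads. Of the 12 sequences tested, 0 were higher and 3 lower, and the list's median of 0.06 over families stood at percentile 59.7 and turned to -0.057 over sequences.

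Copper-related families, whose targets include laccases and other copper proteins, showed no 2-fold difference in sum. miR397 stood at -0.37 (-0.43 to -0.30) under the main scaling and below 0 under each other one, while the sums of miR398 (0.17) and miR408 (-0.14) changed sign between scalings. The miR408 sum joined the 5′ arm of miR408a, at 0.18, with its 3′ arm, at -0.75. That 3′ arm lay below 0 under each scaling. The miR397 sum pooled sequences on both sides of 0. miR397a, for which the laccases of the degradome were listed, stood at 0.62 and was named after its value was seen. Of 6 sequences tested, 1 was lower, miR397b-3p at -1.24 (-1.34 to -1.14), which fell just short of the rule with unscaled reads and was named after its value was seen, and 0 were higher; the list's median of -0.14 over families stood at percentile 43.1 and turned to 0.13 over sequences. miR857 was not among the detected families. Sulfate and phosphate families were scarce. miR395 had 7.47 control and 14.9 chilled reads (0.68, -0.53 to 2.39), miR399 0.75 and 2.5 reads and miR2111 22.2 and 23.4 reads (-0.16, -1.09 to 0.73, of a sign that changed between scalings), so that a difference was not detectable at this depth; the median of 0.68 stood at percentile 63.1.

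No family that targets NB-LRR disease resistance genes differed 2-fold in sum. miR1510 (-0.86, -0.88 to -0.85) and miR2109 (-0.70, -0.93 to -0.48) lay below 0 and miR1507 (0.57, 0.54 to 0.59) and miR2118 (0.44, 0.39 to 0.49) above 0 under each scaling, and miR482 (-0.17) changed sign. miR1510b-5p held 113528 of the 123306 control reads of miR1510. The TIR-NBS-LRR loci of the degradome were listed first for miR1510a-3p, which stood at -0.48. Of 18 sequences tested, 1 was higher (miR1507a) and 1 lower (miR1507c-5p, -1.03, -1.13 to -0.94), of which the first lost its call under the same table total and the second with unscaled reads and with the total without miR3522, and the median of -0.17 stood at percentile 40.4. Families that act on the silencing machinery itself included miR168, which targets Argonaute 1, at 0.75 (0.67 to 0.83), miR403 at -0.84 (-1.72 to -0.06), miR1515 at 0.31 (-0.29 to 0.91) and miR162, which targets Dicer-like 1, at -0.18 (-0.41 to 0.05, of a sign that changed between scalings). Of their 6 sequences tested, 0 were higher and 1 lower, miR162a at -1.15, which lost its call with unscaled reads and with the total without miR3522 and was named after its value was seen. The median of 0.06 over families stood at percentile 57.6 and turned to -0.066 over sequences. The 9 detected families known as cold responsive in other plants, which overlap the lists above, had 10 higher, 10 lower and 34 other sequences, and a median of -0.37 over families at percentile 8.97, which turned to 0.14 over sequences.

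Sequences of 21 nt made up 56.7% of the distinct sequences (95% Wilson interval 51.7 to 61.6), those of 22 nt 17.3% (13.9 to 21.4) and those of 24 nt 16.3% (12.9 to 20.3). By reads, 21-nt sequences took 97.7% of the control table and 97.6% of the chilled table, and sequences starting with T (uridine in the RNA) 93.0% and 95.5%. Without miR3522, an alternative added after seeing the data, 21-nt sequences took 80.7% of control (80.6 to 80.8) and 72.7% of chilled reads (72.6 to 72.8), and 22-nt sequences 14.9% (14.8 to 15.0) and 23.7% (23.6 to 23.8). Most of the latter difference came from miR1509a (29495 control and 48785 chilled reads) and miR1507a (11161 and 28363), out of 68327 and 112084 reads of 22 nt. The 24-nt share went the other way, from 1.15% (1.12 to 1.18) to 1.06% (1.03 to 1.09), with most of its reads from MIR5368-p3 (4393 and 3500), named after its values were seen. The log2 ratio differed with length: its median was -1.28 over 6 sequences of 20 nt, -0.23 over 136 of 21 nt, 0.39 over 40 of 22 nt and 0.44 over 26 of 24 nt. Among 21-nt sequences 13 were higher and 29 lower, among 22-nt sequences 11 and 2, and among 24-nt sequences 5 and 0.

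**Figure D3:**
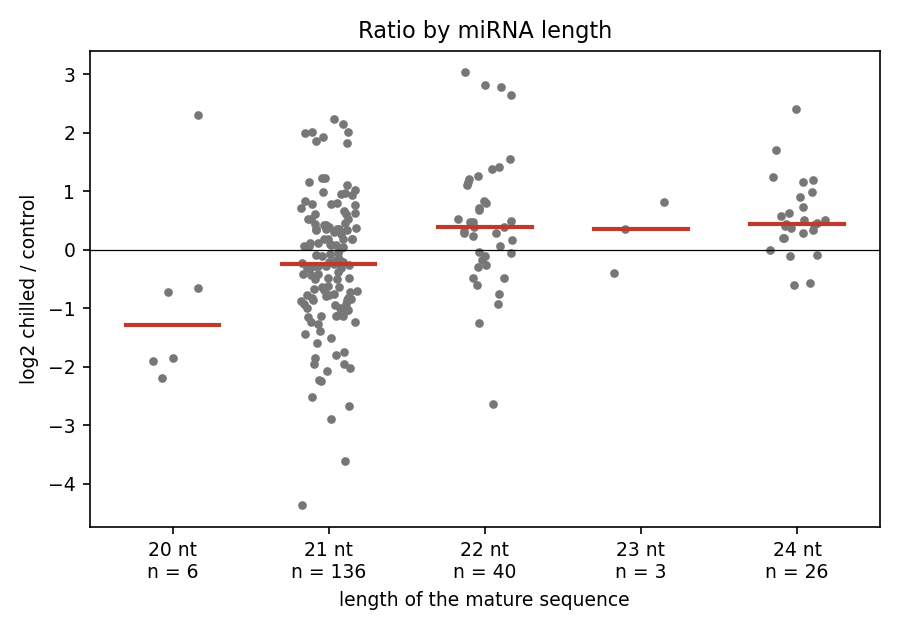
Log2 ratio of chilled to control (vertical axis) by length of the mature sequence in nucleotides (horizontal axis), 1 point per sequence above the minimum, with red bars at the medians. The medians run from -1.28 at 20 nt and -0.23 at 21 nt to 0.39 at 22 nt and 0.44 at 24 nt; the 23-nt class holds 3 sequences.

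The degradome library was used to list transcripts that these miRNAs may cut. The authors' deposited table listed 898 pairs of a miRNA and a transcript, from 89 miRNA sequences of 54 families and 493 transcripts of 275 gene loci. In it, 259 pairs fell in category 0, in which target callers usually place a cut site that is the single highest of its transcript, 38 in category 1, 305 in category 2, 31 in category 3 and 265 in category 4. The authors' p-value was under 0.05 for 143 pairs (15.9%), 132 of them in category 0 and 11 in category 1, and under 0.01 for 16 pairs. Because the library mixed both conditions, it carries no difference between them.

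For families with a textbook target class, 527 of 722 pairs (73.0%) had a target annotated in that class. Shuffling which family goes with which class gave a mean of 31.3 pairs, and none of 100000 shuffles reached the observed number (one-sided permutation p = 1e-05, the smallest they can give). The match was 89.1% in category 0 and 93.8% in category 1, against 53.9% in category 2, 61.5% in category 3 and 72.6% in category 4. Counted once per family and gene locus, 102 of 188 targets (54.3%) matched. All of these pairs rest on a table in which paralogs can share the same degradome reads. Each pair also carries an alignment score, so alignment of sequences alone could bring up a family's class. The shuffles did not separate this from cleavage. Category 4, with 0 pairs at an authors' p-value under 0.05, still matched at 72.6%.

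**Figure D4:**
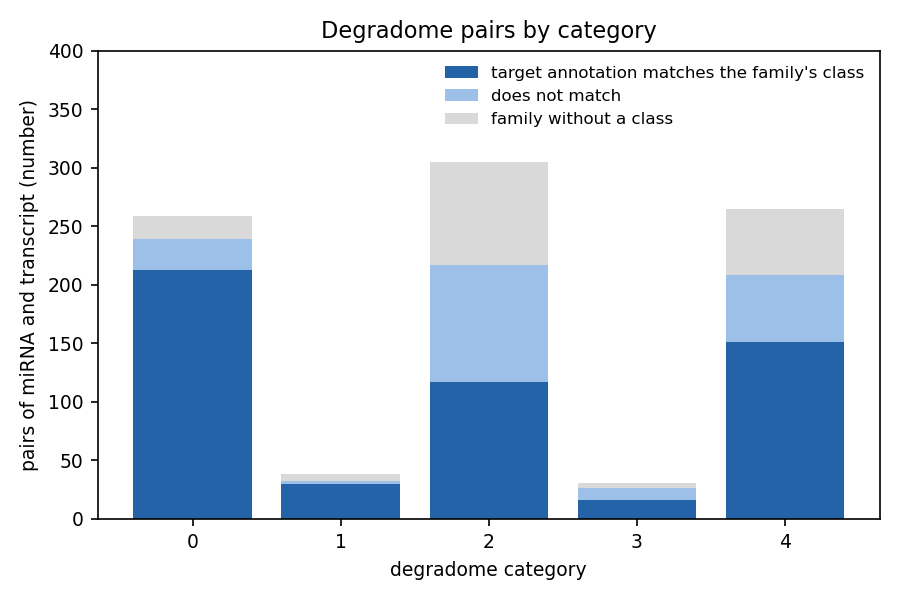
Number of pairs of a miRNA and a transcript (vertical axis) by degradome category (horizontal axis) in the authors' deposited table. Dark blue bars are pairs whose target annotation matches the textbook class of the miRNA's family (213 of 239 in category 0 and 117 of 217 in category 2), light blue bars are pairs that do not match, and grey bars are families without a class.

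In the authors' deposited table the auxin response factors were the clearest targets: miR160 had 11 gene loci, all in category 0, and 10 of them auxin response factors. Its first target was ARF16 (Glyma.19G181900.1, cut at position 2263 of the transcript, alignment score 0, abundance 3460 TPB, the authors' p = 0.00525). miR164a was paired with NAC1 (Glyma.08G173400.1, position 730, 5088 TPB, the authors' p = 0.00769) in category 0 of the deposited table, so the miRNA with more reads after chilling has a NAC factor as its listed target. miR156 had 16 loci annotated as SPL factors among its 23, 10 of them in category 0 or 1, and miR156r itself had Glyma.16G054500.1, an SPL factor cut at position 1497 (749 TPB, the authors' p = 0.0208). The first pair of a locus had an authors' p-value under 0.05 for 3 of the 23 miR156 loci. SPL loci listed first for miR156a in category 0 had an authors' p of 0.267. By the rule for named targets, the first miR156 target was LBD21 (Glyma.18G025600.1, the authors' p = 0.0028) of MIR156d-p3, which is outside the class.

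Other families followed in the authors' deposited table. miR166 had 13 loci of its class among 14, with PHB (Glyma.05G166400.1) first. miR171 had 5 of 5, with the GRAS factor HAM3 (Glyma.03G031800.1) first, and miR1514 had 4 NAC factors of 4. miR172 had 7 of 27 by annotation, or 12 with gene symbols read as well, miR396 had 11 of 25 and miR397 had 9 laccases of 9, with LAC4 (Glyma.03G077900.1) first, in category 3. The first pair of a locus had an authors' p-value under 0.05 for 5 of the 27 miR172 loci, 1 of the 25 miR396 loci and 0 of the 9 miR397 loci. The first target of miR396 was an E1-E2 ATPase (Glyma.03G157700.1), at 21899 TPB, the highest value of the table. miR1510 had 4 TIR-NBS-LRR genes of 4, with Glyma.15G232400.1 in category 0. First targets outside the class were found for miR167 (BRIZ2, category 0), miR398 (a prolyl oligopeptidase, category 0), miR1507 (a pyridoxal-phosphate-dependent enzyme, category 0), miR395 (a dynamin-like protein, category 1), miR159 and miR319 (BGAL13 for both, category 2), miR2118 (a ribosomal protein, category 2) and miR482 (a RING/U-box protein, category 4). In their class were the first targets of miR1515 (DCL2, category 2), miR169 (NF-YA1, category 2), miR399 (PHO2, category 2) and miR2109 (a TIR-NBS-LRR gene, category 4). The authors' p-values of these ran from 0.518 to 0.991, and 0 pairs in categories 2 to 4 had one under 0.05. Listed pairs for the named miRNAs further included miR4413b with a pentatricopeptide repeat gene (Glyma.08G160300.1, category 0, the authors' p = 0.00839), MIR159d-p3 with a pyruvate dehydrogenase subunit, miR169c with NF-YA3 and miR172b-5p with a nucleolin, the last 3 in category 2.

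A degradome target was listed for 17 of the 65 sequences that met the rule of size (26.2%), 6 of them higher and 11 lower, and for 41 of the 148 that did not (27.7%), an odds ratio of 0.92. Among the higher sequences with targets in the authors' deposited table were miR164a, miR169c, miR1507a (an NB-ARC gene) and miR1514b (NTL9-type NAC factors); among the lower were miR156a, miR156r, miR4413a, miR5674a, miR396a-5p (growth-regulating factors) and miR5767 (an F-box gene). These were chosen after their values were seen; miR396a-5p and miR5767 were no longer 2-fold lower with unscaled reads or with the total without miR3522, and miR1514b rests on 3 control and 11 chilled reads. At a minimum of 100 normalised reads the odds ratio was 1.93, and with targets of categories 0 and 1 alone 1.03, both on the other side of 1. No p-value is given, because sequences are not replicates and each condition had 1 library.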

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

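The scalings by DESeq2 size factors, by unscaled reads and by a total without miR3522, the same table total for lists, the shares without miR3522, the classes by symbol and the targets at p under 0.05 were chosen after seeing the data. The number of higher sequences, 30, became 19 with the same table total, 47 with unscaled reads, 63 with no minimum, 7 at a minimum of 100, 14 with 10 reads required in both libraries and 47 over every entry; the number of lower sequences, 35, became 63, 14, 22 and 61 under the last 4 of these. Fewer or more sequences or entries were tested under those 4 (381, 99, 172 and 337 against 213). Other settings kept both counts within 1.5 times. The copper list's median of -0.14 became 0.13 over its sequences, -0.21 with the median ratio set to 0 and -0.37 with the same table total; the NB-LRR list's -0.17 became -0.30, -0.24 and -0.40, and that of the families cold responsive in other plants, -0.37, became 0.14, -0.44 and -0.59. The auxin list's 0.06 became -0.057 over its sequences and -0.16 with the same table total, and the growth list's -0.05 became 0.21 and -0.28. The other list values stayed within their counting error, which was wide: the sulfate and phosphate median of 0.68 became 0.090 over its sequences, and the silencing median of 0.06 turned to -0.066 over its sequences, -0.0083 with the median ratio set to 0 and -0.16 with the same table total, as the auxin median did to -0.011 with the median ratio set to 0. The share of 21-nt sequences was 63.8% at 10 or more normalised reads; without miR3522, 21-nt sequences took 80.7% of control and 72.7% of chilled reads, and first-base T 42.2% and 50.9%. Degradome pairs numbered 297 in categories 0 and 1, 16 at a p-value under 0.01 and 275 as gene loci, each by construction. The class match kept a one-sided permutation p of 1e-05, the smallest the shuffles can give, in each alternative run, at 54.3% (family and gene locus) to 89.7% (categories 0 and 1). The odds ratio of having a target was 1.93 at a minimum of 100 normalised reads, and the cause was not tested. Where no cause is named above, the cause was not tested. Of 210 alternative values of named sequences 159 stayed within counting error, and of 196 of families 123; none that met the rule of size changed sign. Depth limits sequences of few reads: the 10 highest ratios rest on 1 to 11 control reads. The authors' list of chilling-responsive miRNAs, planned with 2 alternatives, was not run. No paired analysis was possible because each condition had 1 library.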

Other observations

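The tests of the miR156 pattern and of both arms of a hairpin were chosen only after their values were seen; those of length and of rarer arms were set before their own results were seen, but the length classes were chosen after the medians by length. The families miR1508, miR4413 and miR5674, chosen after the table was read, had pentatricopeptide repeat, tetratricopeptide repeat and helicase genes among their targets. Together they were listed with 33 gene loci, 9 of them in category 0 or 1, and 15 of the 33 carry identifiers that begin with Glyma.09G17. Each of the 6 loci listed for more than 1 of these families was shared by miR1508 and miR5674. miR5674a (log2 -1.96, 48.5 control and 14 chilled reads) and miR4413a (-1.51) were lower after chilling, while miR1508a stood at 0.66. Of the miRNAs without a fixed class, miR4415a-3p had ascorbate oxidase genes in category 0, and miR4996 had Glyma.13G183200.1 there.

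One hypothesis was that both arms of a hairpin differ in the same direction, as a difference set at the hairpin would give. It was chosen after its values were seen. Its criterion was altered from a permutation p to a bootstrap interval above 0, so that criterion was not set in advance. The hypothesis was tested in 77 distinct hairpins of 45 families with both arms above the minimum. Between the log2 ratios of both arms Spearman's rho was 0.25 (95% bootstrap interval over families 0.00 to 0.51) and Pearson's r 0.29, or 0.19 without the 2 hairpins farthest from the median; the relation was weak, its interval barely cleared 0, and it rests partly on those hairpins. These are correlations across hairpins, which are not independent replicates. In 1 hairpin the arms differed at least 2-fold in opposite directions: miR156a, of 20 nt, stood at -1.84 and its opposite arm, MIR156u-p3, of 22 nt, at 1.21 on 9.5 control and 27.5 chilled reads, a value just under 2-fold with the same table total; the longer arm was the higher one here too.

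Longer miRNAs had higher ratios: the median of 69 sequences of 22 to 24 nt exceeded that of 142 of 20 to 21 nt by 0.69 on the log2 scale (95% bootstrap interval over families 0.33 to 1.08), a difference in which a constant scaling factor cancels, apart from the pseudocount and the few sequences that enter or leave at the minimum. A difference in insert size between the libraries predicts the same within a hairpin, and in 29 hairpins with arms of unequal length the longer arm exceeded the shorter by a median of 1.03 (0.43 to 2.15) and was higher in 24, so a shift in the sizes sequenced may account for the trend. The difference was 0.46 (-0.08 to 0.75) among 92 sequences with a mean of at least 100 normalised reads, which leaves low abundance open, and 0.68 (0.34 to 0.96) as the mean of both GC strata (1.08 and 0.29), whose interval reaches just below the bound set, so GC content stays open as well. Chilling itself, which could alter the processing of longer miRNAs, was not tested apart from the library, since each condition had 1.

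The longer arm is often the rarer one, so low counts were weighed within hairpins too. In 48 hairpins with arms of the same length the rarer arm was not higher: its ratio minus that of the more abundant arm had a median of -0.30 (-0.65 to 0.04), which argues against rarity as the reason the longer arm is higher. Where the longer arm was the more abundant, it was still higher in 9 of 13 hairpins, against 15 of 16 where it was the rarer.

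Within miR156, miR156r (21 nt, -4.36) and miR156a (20 nt, -1.84) were lower, while miR156c (21 nt, 0.42) and the longer opposite arms, pooled (0.82, 0.77 to 0.88), were above 0. The pool's narrow interval is counting error of its sum and not agreement between arms. MIR156o-p3 stood at the pool's value, 0.82, and the opposite arms above the minimum ran from 0.31 to 2.82. Insert size cannot part members of 1 length, and the counting intervals of miR156r and miR156c lay 4.46 apart on the log2 scale. That comparison does not cover miR156a, which stood -1.12 from the median of 5 other 20-nt sequences but above the lowest of them (-2.19), nor the opposite arms, so insert size stays open for both. Reads that only moved between similar members would leave their pool level; the pool of 5 members with a shared core went from 14912 to 6822 reads (log2 -1.37, -1.42 to -1.33, with an upper bound of -1.09 over the scalings run), but miR156a made up most of it, and the 4 members of 21 nt alone pooled to -0.67 (-0.73 to -0.60), with an upper bound of -0.36 over the scalings, so shared reads stay open for miR156r. A biological difference was not tested apart from these, and a single library per condition leaves variation between plants and libraries open.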
